A study of Corynebacterium glutamicum R with 4 samples.

How the data were processed

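Cells of Corynebacterium glutamicum R were grown in 100 ml of a rich medium with 1% glucose in 500 ml flasks at 33 °C, per the labels' protocols. RNA was extracted with a NucleoSpin RNA II kit, and 10 µg was converted to Cy3-labelled cDNA by indirect labelling, per the labels' protocols. The series has 4 arrays, 2 of the wild type and 2 of the sigD deletion mutant, in exponential phase. The submitters describe 2 independent experiments.

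Each array's scanner output holds spot intensity values, background-subtracted and processed by Agilent Feature Extraction, per the file headers. The version was 10.5.1.1 per the file headers and 10.5.5.1 per the submitters' processing notes, and the difference was not settled. A series-wide table holds the authors' deposited log2 values for the same arrays. Set against the scanner values, its differences between the arrays of a pair correlated at 0.9993 and 1, and 99.9% of them lay within 0.01 of a constant offset of 0.11 and 0.572. In the table the wild type and deletion values of a pair have opposite signs, so it is centred within pairs, and the column medians were -0.0235 and -0.11 in the wild type and 0.0235 and 0.11 in the mutant. Its direction is borne out by this comparison, while the scaling step behind the offsets is not given in the sources used here.

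Each array had 45220 spots, of which 1417 were control spots and were left out. Outlier readings, 376 of 175212, were left out too, and no spot was saturated. Processed signals were taken as log2, the 75th percentile of each array was subtracted, and spots of a probe were averaged. A probe was tested where at least 50% of its spots were well above background on both arrays of at least 1 group. This left 3256 of the 3278 numbered probes and 32231 tiled probes. The lowest signal called well above background was 11.8 and 25.9 on wild type arrays 1 and 2, and 12.2 and 9.64 on deletion arrays 1 and 2. The median of the negative control spots was 2.68, 6.67, 2.69 and 2.30 in the same order.

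Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment) in R 4.3.3, with the group as the only term and a threshold of 0.05 on the adjusted p. The numbered and the tiled probes were fitted separately, and the numbered probe was taken as the unit in place of the gene once the probe names were seen. Data were simulated with the real means of the 3256 numbered probes and with noise independent between probes and arrays. The variance of each probe was drawn from the distribution that limma fitted over these probes, which is the model its test assumes. The real arrays need not meet this, so the simulation does not measure the power of the real fits. The fit of 2 arrays against 2 recovered 83 of 100 probes changed 2-fold and 98 of 100 changed 4-fold, with 7 false calls. With 2 arrays against 1 it recovered 67 and 94, with 10 false calls. Slide and scan coincided with the replicate number and each held both groups, so the block fit is at once that of the slide, the scan and the replicate. Values within slides rest on the shared slide and do not show that cultures were paired. For bounds, a level not well above background was set to the higher of its own and the lowest signal called well above background on its array.

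The design, the alternatives and the rule for single probes were fixed before the data were examined. The rule took the 12 largest falls and 8 largest rises among probes that passed the test and whose groups did not overlap. At most 2 names per direction are printed because the files do not pair names with genes. The reference table given covers 3079 genes of another strain and matched 0 of the probe names. For that reason the 18 gene lists fixed beforehand, sigD itself and the genes next to it were not analysed here, and the camera and fry set tests were not run.

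Alternatives were quantile normalisation, median centring, normexp background correction (offset 50, on the median signal and median background, the columns used here), the deposited log2 table (fitted with the pair as a block, because its values are centred within pairs), other filters on dim probes, the block, an intensity trend with a robust prior, and leaving out each array. Fits of all probes together, of crossed pairs and without the last 77 numbers were added after the data were seen, as were the tests of neighbouring numbers and of tiled runs and all alternatives for the tiled probes.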

Results

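RNA levels were measured in Corynebacterium glutamicum strain R, a soil actinobacterium used for amino acid production, in the wild type and in a mutant lacking sigD. The sigD gene encodes an extracytoplasmic function sigma factor, a subunit that directs RNA polymerase to a particular set of promoters. Total RNA from exponentially growing cells was labelled with Cy3 and hybridised to 1-colour Agilent arrays. Each group had 2 arrays, replicates 1 and 2. Both arrays of replicate 1 lay on 1 slide and both arrays of replicate 2 on the other slide. The median processed signal of the non-control spots was 530.4 and 661.4 in wild type replicates 1 and 2, and 494.3 and 455.9 in deletion replicates 1 and 2. The share of these spots well above background was 91.6%, 83.0%, 91.1% and 90.9% in the same order. The number of arrays limits the precision of every value given here. The submitters describe 2 independent experiments and do not say what was kept separate between them. P-values are therefore read as weighing the group difference against the spread between these arrays, which limma estimates partly from other probes.

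The array carried 3278 probes named by a running number, each printed at least 2 times, and 18462 forward and 18449 reverse tiled probes, each printed once. The files pair none of these names with genes, so sigD and its neighbours are not named here and probes stand for themselves. The comparison of the mutant with the wild type asked which transcripts depend on sigD in exponential growth.

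The RNA measured by a pair of numbered probes with consecutive numbers was almost completely lost in the deletion mutant. CGR0763 fell by 10.34 on the log2 scale (SE 0.30, limma adjusted p = 0.000498, lower on both slides), which is 1296-fold. Its processed signal was 32305 and 44942 on the wild type arrays, and 34.9 and 19.0 on the deletion arrays. CGR0762 was not well above background on either deletion array and was, with the deposited background subtraction, at least 257-fold lower than in the wild type (limma adjusted p = 2.18e-05). Its signal was 2942 and 3449 in the wild type, and 2.49 and 1.99 in the mutant. The bound sets the mean normalised level in the wild type against, for each deletion array, the higher of the probe's own level and the lowest signal called well above background there. With the slide as a block the adjusted p was 0.00212 for CGR0763 and 0.00013 for CGR0762. Within slides 1 and 2, CGR0763 differed by -9.78 and -10.90, and CGR0762 was at least 229-fold and 288-fold lower. Under normexp background correction, which adds an offset of 50 to every signal and so shrinks differences at dim probes, the bound does not apply and the fitted difference of CGR0762 was -5.75 on the log2 scale. The level of the pair went with the label on all 4 arrays. Whether the pair includes sigD was not analysed here.

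Another numbered probe, far from this pair in the numbering, fell by 7.10 on the log2 scale (SE 0.23, limma adjusted p = 0.000564), or 137-fold. Its signal went from 24289 and 40639 in the wild type to 232 and 173 in the mutant, and with the slide as a block its adjusted p was 0.00373. The probes numbered next to the lost pair changed far less. The number before it rose by 0.76 (SE 0.11, limma adjusted p = 0.0316), and the number after it fell by 1.32 (SE 0.14, limma adjusted p = 0.0156). These calls on the flanking numbers ended when any 1 array was left out, with adjusted p up to 0.30 for the number before and 0.17 for the number after, while their differences stayed at 0.70 to 0.83 and -1.45 to -1.19. The second number after it differed by -0.39 (SE 0.23, limma adjusted p = 0.403).

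**Figure D1:**
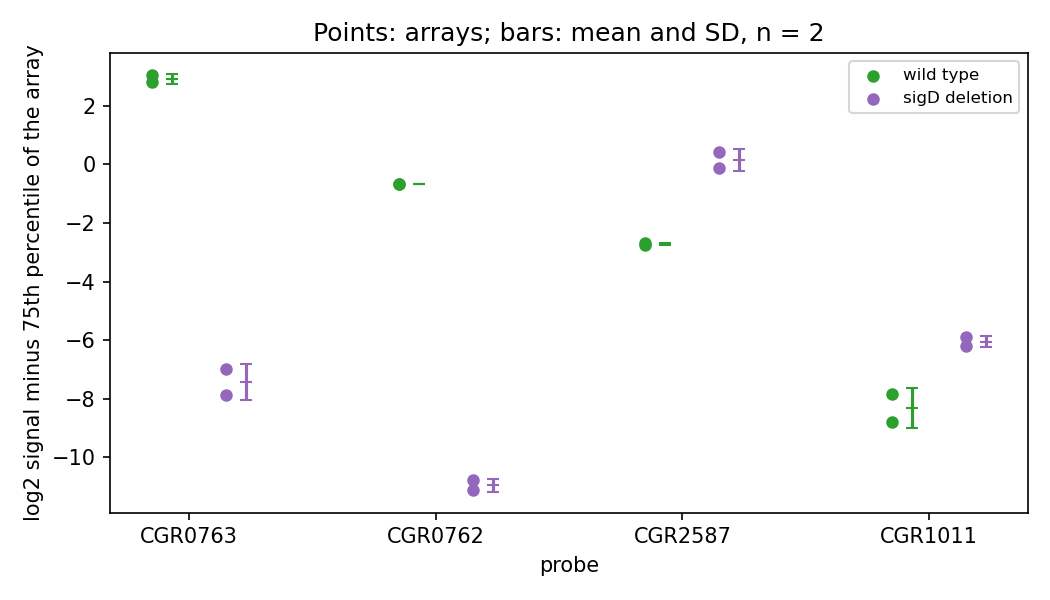
Log2 signal minus the 75th percentile of its array for the 2 printed probes with the largest falls and the 2 with the largest rises. Points are single arrays, bars the mean and SD of 2 arrays, and levels are to be compared within a probe; in CGR0763 and CGR0762 both deletion arrays lie far below both wild type arrays.

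Over all numbered probes, 120 of the 3256 tested differed between the groups in limma, of which 83 rose and 37 fell in the mutant. The median rise was 0.98 and the median fall -1.26 on the log2 scale. At least a 2-fold change was seen in 61 of them, 37 that rose and 24 that fell. In all 120 both deletion arrays lay beyond both wild type arrays, from which it follows that they moved the same way on both slides. That separation was found in 54% of all tested probes, against 33.3% by chance for 2 arrays against 2. At an unadjusted p under 0.05 there were 636 probes. The slide as a block gave 118 probes, of which 106 were among the 120. The count and the excess of rises depended on single arrays. Without wild type replicate 1 or 2 there were 6 and 3 probes, all of which fell, and without deletion replicate 2 there were 4, of which 1 rose. Without deletion replicate 1 there were 99, 36 that rose and 63 that fell, and 55 of them were among the 120. In each of these 4 fits the direction of the 120 could not change, because both groups were already separate. With all probes fitted together 3 passed, and all 3 fell.

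The strongest rise was that of CGR2587, which was 7.27-fold higher in the mutant (log2 2.86, SE 0.19, limma adjusted p = 0.00937, higher on both slides). Its adjusted p was 0.0128 with the slide as a block, and 0.12 and 0.17 without wild type replicates 1 and 2, where the log2 difference was 2.84 and 2.88. CGR1011 rose (fitted log2 2.27, SE 0.32, limma adjusted p = 0.0309) and was well above background on 1 of the 2 wild type arrays and both deletion arrays. With the other wild type array set at its lowest signal called well above background, CGR1011 was at least 3.33-fold higher in the mutant under the deposited background subtraction. Its adjusted p was 0.0241 with the slide as a block, and between 0.061 and 0.17 when an array was left out. Under normexp background correction, with its offset, that bound does not apply and its log2 difference was 0.87. The 12 largest falls ran from -10.34 to -1.55 and the 8 largest rises from 1.41 to 2.86 on the log2 scale. A group of 4 falling probes with consecutive numbers moved together, by -3.25 to -1.29, and 3 rising ones by 1.41 to 1.65.

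Changed probes lay side by side in the numbering. Of the 120, 51 had a neighbour in number that changed in the same direction, 39 that rose and 12 that fell. When the calls were shuffled over the tested probes 100000 times, the mean was 4.9 and the highest 20 (permutation p = 1e-05, one-sided, the smallest that these shuffles can give). These shuffles break any link between neighbouring numbers, so the p-value shows only that calls cluster in the numbering. The end of the numbering held many of the rises, including runs of 12, 7 and 4 consecutive numbers that rose. Of the last 77 numbers, a stretch chosen after its values were seen, 33 rose and none fell, which is 39.8% of all rises in 2.35% of the numbers. Their median difference was 0.67, and 0.77 and 0.57 within slides 1 and 2. The stretch was not raised throughout. The first 30 numbers had a median of 0.99 and 25 passed the test, the next 13 had a median of 0.04 and 0 passed in limma (2 at an unadjusted p under 0.05), and the last 34 had a median of 0.58 and 8 passed. A fit without the last 77 numbers called 65 probes, 35 that rose and 30 that fell, all of them among the 120. With the stretch in the fit, 50 rises and 37 falls lay outside it. Some calls outside the stretch therefore ended when it was left out. At an unadjusted p under 0.05, 583 probes outside it passed with the stretch in the fit and 577 without it. The adjusted p of a probe depends on the other p-values in the fit, and 53 of the 77 had an unadjusted p under 0.05. How far this accounts for the ended calls was not tested separately.

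**Figure D2:**
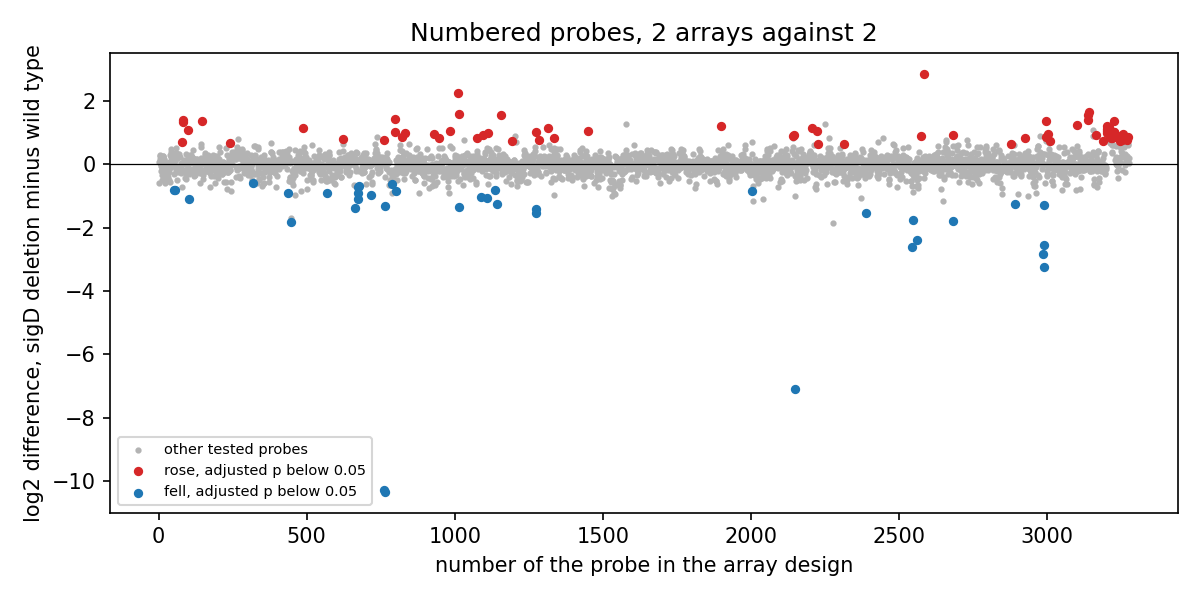
Log2 difference between the sigD deletion and the wild type (vertical axis) for each tested numbered probe along its number in the array design (horizontal axis). Blue points fell and red points rose at an adjusted p under 0.05, and grey points are the other probes; the lost pair lies lowest and red points crowd at the highest numbers.

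The tiled probes gave a separate measurement of the same RNA, since they were printed as other spots. In the tiled series 5 of 32231 tested probes differed in limma, and all 5 fell. At an unadjusted p under 0.05 there were 3556, and 1 probe, the second of the forward probes given next, passed with the slide as a block. Consecutive forward probes, 2 in number, were not well above background on either deletion array and were at least 942-fold and 896-fold lower (limma adjusted p = 0.0088 and 0.00227). The 6 forward probes after them differed by -1.65 to -1.1, and the probe before them by 0.62. Consecutive reverse probes, 3 in number, differed by -7.81, -6.60 and -6.72 (limma adjusted p = 0.0118, 0.0145 and 0.0088). Without an array between 0 and 510 tiled probes passed, with 0 in limma without deletion replicate 1 or 2 (5060 and 2144 at an unadjusted p under 0.05) and 510 without wild type replicate 1, of which 116 rose. Rises among the tiled calls also came with other settings, 39 of 130 with normexp and 73 of 209 with an intensity trend.

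**Figure D3:**
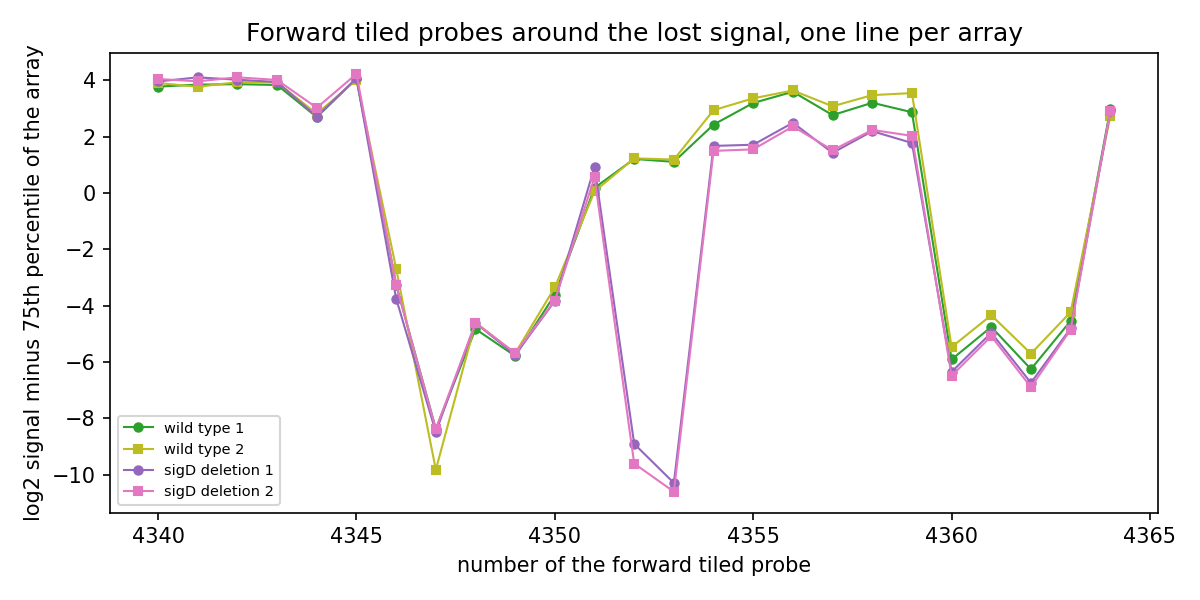
Log2 signal minus the 75th percentile of its array (vertical axis) for consecutive forward tiled probes (horizontal axis), with 1 line per array. At 2 probes both deletion arrays are not well above background, and at the 6 probes after them the deletion arrays lie lower by 1.1 to 1.65.

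Runs of consecutive tiled probes with at least a 2-fold difference in the same direction on both slides were counted without a test of single probes. At a length of at least 3 there were 32 runs, 17 lower and 15 higher in the mutant, holding 178 probes. The longest lower run had 32 probes and the longest higher run 8. Shuffled orders gave 0.008 runs on average and 1 at most (1000 shuffles, permutation p = 0.001, one-sided, the smallest they can give). The signal of consecutive probes correlated at 0.78 in the forward and 0.79 in the reverse series. Shuffling breaks this link, so the p-value shows only that differences cluster along the series and does not bear on their cause. The same count for differences in opposite directions on the slides was 12 runs, the longest of 37 probes. Among the numbered probes 47 differed at least 2-fold in the same direction on both slides, and 20 in opposite directions.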

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

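The fits of all probes together, of crossed pairs, without the last 77 numbers and of the tiled probes under other settings were chosen after the results were seen. The 120 numbered probes became 193 with median centring (148 rose, 45 fell), 3 when all probes were fitted together and 65 without the last 77 numbers. The last fit also lost calls at other numbers, while those with an unadjusted p under 0.05 went from 583 to 577. The cause was not tested separately. The 61 with at least a 2-fold change became 93 with the deposited log2 table and a block together and 3 with all probes together. Other planned settings that used all 4 arrays gave 94 to 154 probes. Leaving out 1 array gave 3 to 99 probes and 3 to 80 with at least a 2-fold change, in fits where the lone array is assumed to vary like the other group. The replicate block, which is also the slide, gave 118 probes, 63 of them at least 2-fold changed, and ended no call of the numbered probes described singly, but 4 of the 5 tiled calls. Deviations of same-numbered arrays correlated at -0.29 over numbered and 0.0046 over tiled probes, so whether the numbers are crossed is open; crossed pairs as a block, which lower the residual by their choice, gave 181 probes.

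The 5 tiled probes became 31 with quantile normalisation, 49 with median centring, 130 with normexp, 66 with the deposited table and a block together, 8 with probes well above background on all 4 arrays, 1 with the replicate block and 209 with an intensity trend, and the cause was not tested. Leaving out 1 array gave 0 to 510. The 32 tiled runs numbered 24 to 36 under the normalisation, background, table and filter settings, the only ones run. The median difference of all numbered probes was 0.0132 with the 75th percentile, 0.139 with median centring and 0.161 in the deposited table, so the balance of rises and falls moves with the scaling.

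The fitted difference of CGR0763 lay between -10.8 and -8.44 and that of CGR0762 between -10.4 and -5.75, past the threshold in every setting that tested them. The rise of CGR2587 missed the threshold without either wild type array and with all probes together (adjusted p up to 0.17), and that of CGR1011 in each fit without 1 array and with all probes together (up to 0.18). The number before the lost pair also missed it with normexp (0.083) and an intensity trend (0.051), and both flanking numbers missed it with all probes together (0.22 and 0.15). Signal near background makes the fall of CGR0762 a bound. Gene lists, sigD, its neighbours and the median over probes of a gene were not run, because no probe could be tied to a gene.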

Other observations

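All tests in this part were chosen after the result was seen, except that of background subtraction at dim probes. A further set of 15 probes, each printed 10 times, was not part of the comparison above. In a limma fit together with the numbered probes 1 of them passed and fell by 0.77 on the log2 scale (SE 0.11, adjusted p = 0.0297, -0.71 and -0.83 within slides 1 and 2). The highest difference among the others was 0.42 (adjusted p = 0.128).

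Of the 20 numbered probes that differed at least 2-fold in opposite directions on the slides, 19 were lower in the mutant on slide 1 and higher on slide 2. Their differences reached -4.48 on slide 1 and 4.09 on slide 2, and none of the 20 passed the test between the groups.

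The near-complete loss at CGR0763 and CGR0762 may come from removal of the DNA segment, from loss of transcription or from faulty spots. Faulty spots are argued against by 2 consecutive tiled probes, printed elsewhere, that fell by at least 5 on the log2 scale on both slides at a similar relative place (23.3% and 23.6% of the way along the series). Removal stays open for CGR0762 and these tiled probes, whose highest deletion signal was 0.753 times the lowest signal called well above background, though 2.34 times the 95th percentile of the negative control spots. At CGR0763 every deletion spot was well above background (the lowest 1.81 times that lowest signal, the highest 11.6 times that percentile). Removal there would need signal from other RNA, which was not tested. The same holds for the third lost probe, whose signal averaged over spots was about 18 times that lowest signal on the lower of the 2 deletion arrays. The sigD genotype is the biological difference the design names, and its effect on transcription there was not tested apart from removal.

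Most of the last 77 numbers were higher in the mutant (69 of 77, median 0.67 on the log2 scale), in a first part of 30 and a last part of 34 around 13 numbers with a median of 0.04. A constant scaling difference between arrays, which would shift all numbers alike, is argued against. No 77 consecutive numbers outside the stretch had a median above 0.096. The stretch was chosen for its height, so its rank among such windows is no test of it. Scaling that depends on signal was not examined. One change of copy number of the whole stretch as the only cause is argued against, since 32.5% of its probes lay within 2 of their standard errors of its median. A change of copy number of a part stays open and was not tested. In the first 30 numbers all 30 were higher, with a median of 0.99, and 0.995 and 0.952 within slides 1 and 2. The stretch could lie outside the tiled sequence, as a separate replicon or an added set of probes might. Of its probes 54.5% were higher by at least 0.5 on both slides, against at most 12.7% of the tiled probes in any stretch of the same relative length. This cannot decide the question, since a tiled series may hold probes off the transcribed strand, which would lower its share. Median signals of forward and reverse tiled probes were also lower, 283 and 352.3 against 3074 for numbered probes. An effect of the sigD genotype on transcription of the stretch remains open and was not tested separately.

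The wild type arrays differed more from each other at dim probes than the deletion arrays did, which does not show which of them scattered. Over the dimmest sixth of the tiled probes the SD of the difference between the wild type arrays was 0.771, against 0.484 between the deletion arrays. The ratio of these SDs was 1.59 with the deposited background subtraction and 1.8 after normexp correction. Normexp also uses each array's own background, so the test cannot exclude background subtraction on wild type replicate 2 as the cause. The median of wild type replicate 2 minus replicate 1 was -0.315 in the dimmest sixth and 0.0168 in the brightest. Over the brightest sixth the ratio was 0.865, so the larger difference between the wild type arrays was not seen at bright probes. This ratio cannot exclude a difference between the wild type cultures, since the deletion cultures may differ as much. The negative control median of 6.67 on wild type replicate 2, against 2.68 on the other wild type array, leaves a higher background as open, and no biological explanation was tested.

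The forward and reverse series may run along the same chromosome in opposite numeric order. The correlation across probes, which are not independent, of wild type log2 signal between mirrored numbers was -0.44 at the best offset and at most 0.093 in size at distant offsets. The numbered probes may follow the forward order: the median distance from a tiled run to the nearest changed numbered probe of the same direction was 0.36% of the series, against 1.2% under circular shifts (permutation p = 1e-04 over 10000 shifts, the smallest they can give). Whether the opposite strand changed with a run was not settled, with the same direction in 59.4% of the 32 runs (permutation p = 0.29, one-sided).

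The arrays can be parted into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 120 probes, a count that only this 1 of the 3 splits reached. Wild type 1 and deletion 2 against wild type 2 and deletion 1 gave 14, and slide 1 against slide 2 gave 0.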
